A study of Saccharomyces cerevisiae BY4741 with 156 samples.

How the data were processed

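RNA 3′ ends were read from libraries of *S. cerevisiae* strain BY4741 that expressed a candidate RNA nucleotidyltransferase tethered to a reporter RNA, a serine tRNA with an MS2 stem loop. Per the labels, RNA was ligated at its 3′ end to a primer with a random heptamer, reverse transcribed and sequenced. The deposited per-library files, made by the authors, hold whole-number counts for each insert, with no normalization; an insert is the reporter end found (CCA, CC, C, none or not recognised) and the sequence after it. The steps from reads to inserts are not given in the sources used here. Whether the counts are reads or distinct heptamers is not stated. A heptamer can take 16384 sequences; the highest count of 1 tail was 13199, and 34 untailed ends in 24 libraries had counts above 16384, up to 19402. The counts level off near that number but are not strictly distinct heptamers, and counts of abundant untailed ends may be compressed. The correction for repeated heptamers named below assumes distinct heptamers and sets counts above 16384 just under it.

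The authors' deposited summary table gives percent of added nucleotides, percent tailed and a tail length score in nucleotides per library. It was used only for comparison and for the construct names. For tails of 5 nucleotides or more in 149 libraries, the A share computed from the per-library files differed from the authors' by a median of 0.00255 percentage points and by at most 4.50, and 137 libraries lay within 0.5 points.

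A tail was an insert of 1 nucleotide or more after CCA, without unread bases, with T written as U. Measures per library were the percent of added nucleotides that were A, C, G or U, summed over all tails; the mean tail length in nucleotides; and the percent of adjacent nucleotide pairs within tails that were UG or GU. Libraries with fewer than 100 tails were left out, which removed 1 of 156 libraries, an empty vector library with 25 counts and 1 tail. The 155 libraries used formed 50 groups by the enzyme label; 45 groups held 2 or more libraries, and 5 held 1. A further label, here called the run (7 sets), was read from the deposited file names.

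Total counts per library ranged from 4030 to 1016629 (median 79002) and tails from 244 to 165208 (median 11364). A median of 18.7% of counts, and up to 77.6%, had an end that was not recognised and did not enter the tails. For a group of 1 library, a share is given with its 95% Wilson confidence interval over added nucleotides. Nucleotides of a tail and molecules that share a heptamer are not independent, so intervals cover counting error only.

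Each group of 2 or more libraries was compared with reporter only (44 groups, 150 libraries, 105 residual degrees of freedom) with limma 3.58.1. It was fitted to the log2 odds of each share with a pseudocount of 0.5 and to the log2 mean tail length. P-values are two-sided, with Benjamini-Hochberg adjustment over groups and the 4 nucleotides, or over groups for tail length, and a threshold of 0.05. Planned comparisons of single measures used two-sided exact permutation tests of the difference in means. Counts of the 64 overlapping trinucleotides within tails were compared between RDE-3a and its DADA mutant with edgeR 4.0.16 (quasi-likelihood test, low counts filtered, total trinucleotide counts as library size). The share of variance between libraries explained by enzyme was tested with 100000 permutations. Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

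The groups, measures, tests, enzyme family lists and naming rule were fixed before the data were examined. For each nucleotide and for tail length, the rule named up to 6 groups with the largest difference from reporter only, among those past the threshold with every library beyond the most extreme reporter-only library. It also named every RDE-3 group, both members of each paralog pair, up to 4 members per family, and the 6 trinucleotides with the largest and the 6 with the smallest log2 fold change past the threshold. Families were described by how many members passed, over all groups and adjusted over the list alone.

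The screen was tested on 20 simulated datasets. A simulated log2 difference of 1 in a nucleotide share was called in 30.6% of cases, of 2 in 83.8% and of 4 in 99.9%; a log2 difference of 1 in tail length was called in 92.2%. Without a simulated difference, a higher nucleotide share was called in 0.999% of cases and a longer tail in 0%. False calls made up 0.355% of all calls. The simulated screen gave all groups the same spread, shifted each share independently and had no outlying reporter-only library. These rates therefore need not hold for the real screen. In the simulated trinucleotide counts, 100% of differences above 2 were called, with a median error of 0.273 on the log2 scale. That simulation gave all trinucleotides the same spread. Some real ones varied widely, such as UUU with DADA (0.347% ± 0.508), so its rates need not hold for the real test either.

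Alternatives were a minimum tail length of 3 or 5 nucleotides, each distinct tail counted once, shares averaged over tails, other minimums of tails, a pseudocount of 5, run as a covariate or within-run permutation, replicate number as a block, reporter only and both DADA groups as control, TMM, no filter, DESeq2, and leaving out libraries or runs in turn. After the data had been seen, a correction for repeated heptamers, the use only of libraries in the authors' table, and averaging libraries that share a name in that table were added. Libraries of a group were checked for duplicates by comparing insert counts within 220 pairs; no pair had p above 0.05, and the lowest chi-square per degree of freedom was 2.35. An earlier version of this check, on tails alone, had too few counts in some pairs and was replaced after its result was seen.

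Replicates are cultures from single colonies per the labels. In the authors' table, 21 groups have fewer construct names than libraries, so several libraries share a name, and p-values measure only the spread between these libraries.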

Results

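The data describe which nucleotides each enzyme added to the 3′ end of a tRNA reporter to which it was tethered in yeast. Groups comprised wild-type enzymes from *C. elegans*, *S. pombe*, *S. cerevisiae*, *A. nidulans*, *C. albicans*, *N. crassa* and human, mutants of *C. elegans* RDE-3, and cells with the reporter only. The 155 libraries fell into 50 groups of up to 8 libraries. Total counts ranged from 5910 to 138642 in run 1, 48867 to 237184 in run 2, 31915 to 1016629 in run 3, 30408 to 158545 in run 4, 21386 to 734662 in run 5, 4030 to 223526 in run 6 and 51067 to 137424 in run 7.

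Reporter-only libraries carried short tails made mostly of A. Of the nucleotides added, 76.0% ± 7.64 (SD, n = 3) were A, 12.4% ± 4.06 G, 6.25% ± 1.75 C and 5.32% ± 1.96 U. Mean tail length was 1.99 ± 0.0801 nucleotides, and UG or GU made up 3.00% ± 1.18 of adjacent pairs. The A share of reporter-only replicate 2, in run 3 with 541189 total counts, was 67.4%, against 78.6% and 82.0% in the other replicates.

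Enzyme identity accounted for 94.4% of the variance of the 4 nucleotide shares among 150 libraries, against at most 53.7% when labels were permuted (permutation p = 1e-05, the smallest they can give). Some groups were spread widely: the U share ranged from 4.06 to 73.6% among TUT4 libraries and from 29.6 to 50.4% in PUP-3, and the C share of *N. crassa* NCU08022.7 ranged from 0.560 to 47.1%, the highest being replicate 1, whose construct name in the authors' table differs from that of the others.

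The screen asked which nucleotides each enzyme adds. Of 44 groups tested against reporter only with limma, 25 had a higher A share, 10 a higher U share, 3 a higher C share and 1 a higher G share, and 20 had longer tails. A lower share was called for A in 11 groups, C in 28, G in 38 and U in 23. Shares of a library sum to the whole, so that a rise in one nucleotide lowers the others. No group had shorter tails. Reporter-only libraries were in runs 1 and 3 only, so groups such as cutA, GLD-4 and Cid16 shared no run with them. For such groups a difference between runs is part of the comparison. With run as a covariate, 47 of 48 single enzymes and trinucleotides kept their direction and side of the threshold. The trinucleotides among them compare RDE-3a with its DADA mutant and do not involve reporter only. The enzymes among them are those named by the rule or taken from the family lists, not all groups called. The count for A rested on reporter-only replicate 2, without which it was 14, and was 12 in tails of 3 nucleotides or more and 11 with the DADA mutants added to the control.

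**Figure D1:**
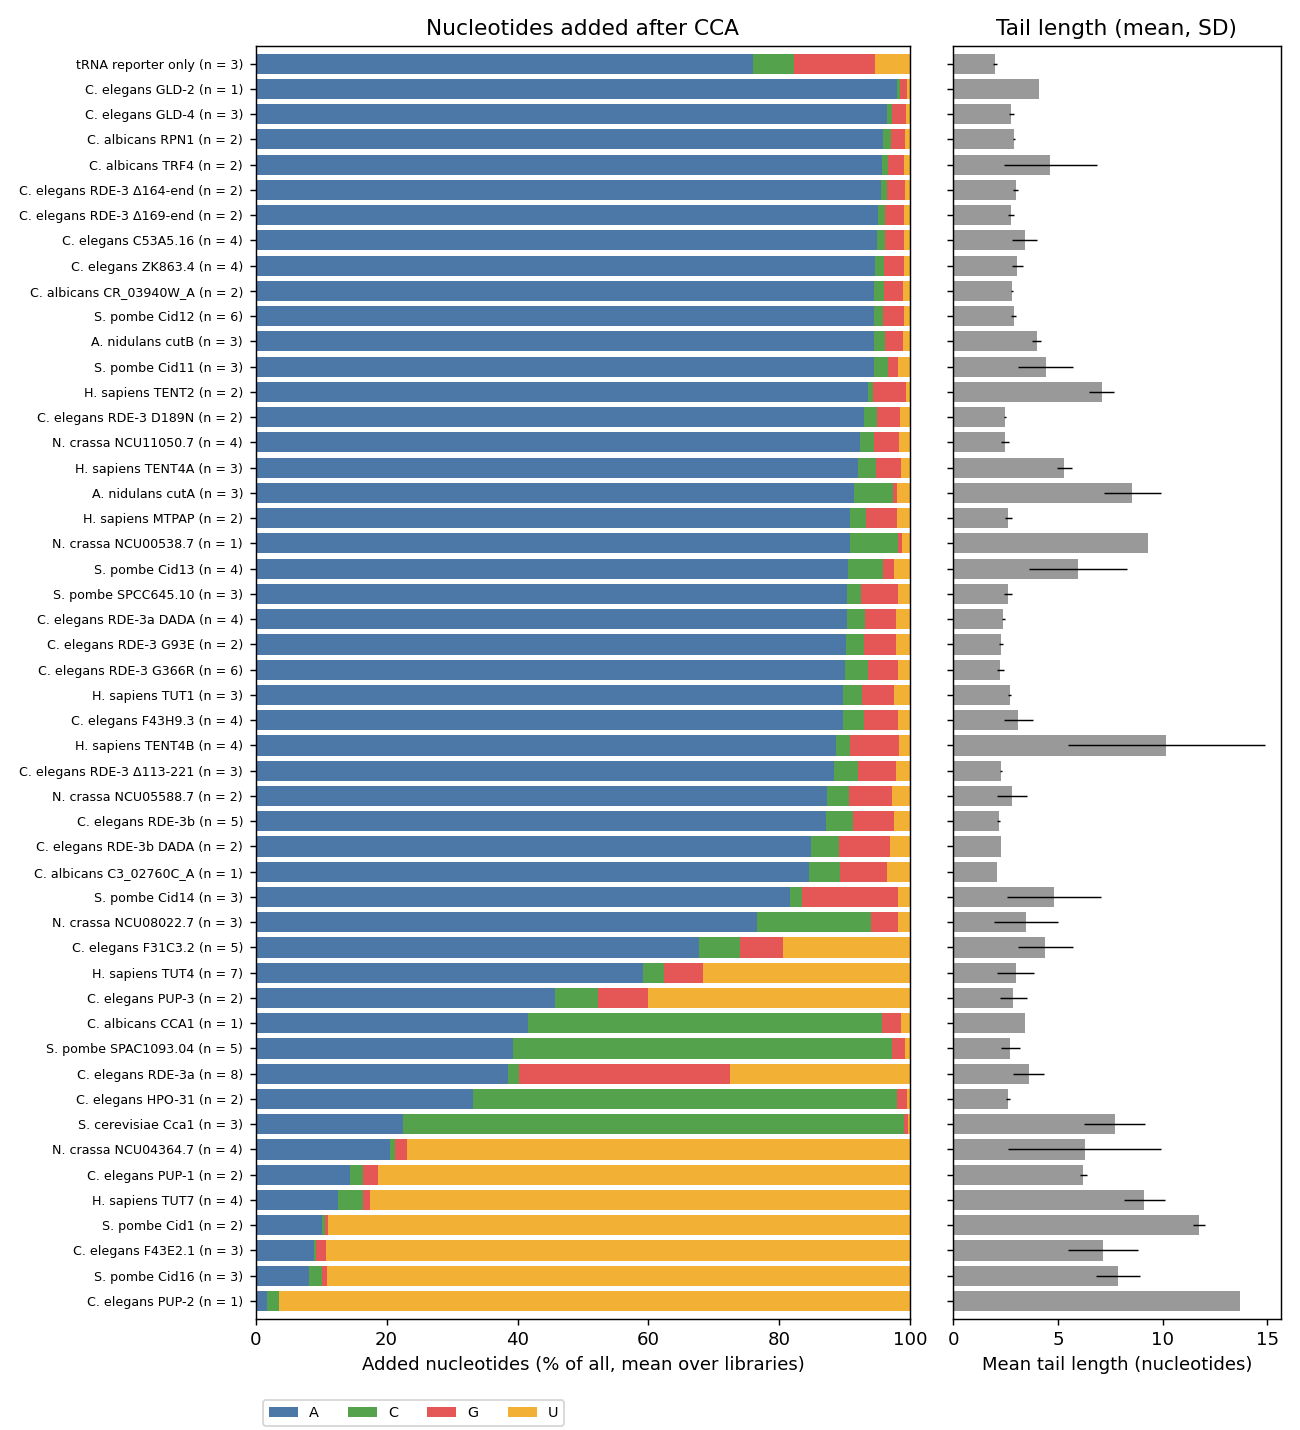
Nucleotide shares (percent of added nucleotides) and mean tail length (nucleotides) for each group; bars are means over libraries, lines on the tail lengths are SD, and bars without a visible line are groups of 1 library or have an SD too small to show. U-rich groups such as Cid1 (88.9% U), C-rich groups such as Cca1 (76.7% C) and RDE-3a, with 32.2% G and 27.5% U, stand out among groups with mostly A.

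In percentage points, the tested groups with the largest rise in A share were *C. elegans* GLD-4, *C. albicans* RPN1 and TRF4, the RDE-3 truncations Δ164-end and Δ169-end, and *C. elegans* C53A5.16. GLD-4, a cytoplasmic poly(A) polymerase, gave 96.5% A ± 0.729 (SD, n = 3; limma adjusted p = 1.00e-05). RPN1 gave 95.8% ± 1.34 (n = 2), TRF4 95.6% ± 2.07 (n = 2) and C53A5.16 94.96% ± 1.18 (n = 4). On the log2 odds scale of the test, *C. elegans* ZK863.4 (2.580) ranked just above Δ169-end (2.575) and C53A5.16 (2.560). A higher A share was also called for the DADA mutant of RDE-3a, so the call alone does not show that the enzyme added A.

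In the TRF4/TENT4 list, which holds relatives of a nuclear poly(A) polymerase, 4 of 5 tested members had a higher A share and 4 had longer tails. Human TENT4A gave 92.1% A ± 1.12 (n = 3) and TENT4B 88.7% A ± 1.08 (n = 4). Cid14 was not called, with 81.6% A ± 0.816 (n = 3; limma adjusted p = 0.486), but was called when each distinct tail was counted once (log2 difference 1.96, limma adjusted p = 0.000884). All 3 tested members of the GLD-2/Cid11/Cid13 list had a higher A share and longer tails: human TENT2 gave 93.5% A ± 0.680 (n = 2), *S. pombe* Cid11 94.5% ± 0.383 (n = 3) and Cid13 90.5% ± 0.137 (n = 4). The single GLD-2 library had 98.0% A (95% Wilson interval 97.8 to 98.2). Human mitochondrial poly(A) polymerase MTPAP gave 90.9% A ± 1.62 (n = 2), and *S. pombe* Cid12 94.5% ± 1.12 (n = 6). Both *A. nidulans* enzymes had a higher A share, with 91.4% ± 0.350 for cutA and 94.5% ± 0.471 for cutB (n = 3 each), and longer tails. The A calls of cutA, MTPAP, TENT2, TENT4A, TENT4B, Cid11 and Cid13 were lost in at least 1 of these settings: tails of 3 or of 5 nucleotides or more, the DADA mutants added to the control, or reporter-only replicate 2 left out; without replicate 1 the TENT4B call was lost as well (log2 difference 1.35, limma adjusted p = 0.0547). In tails of 3 nucleotides or more the TENT4B difference was −0.064 and that of Cid14 −0.97 on the log2 scale.

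Uridylyltransferases formed the next largest set. Of 7 tested members of the list of enzymes with such names, 6 had a higher U share, and 4 had longer tails (5 when adjusted over the list alone). *S. pombe* Cid1, a poly(U) polymerase, gave 88.9% U ± 0.9502 (n = 2) in tails of 11.7 ± 0.306 nucleotides. Cid16 gave 89.1% U ± 3.22 (n = 3), human TUT7 82.5% ± 2.19 (n = 4), *C. elegans* PUP-1 81.3% ± 0.239 (n = 2) and PUP-3 40.0% ± 14.7 (n = 2). The call for TUT4, at 31.7% U ± 32.8 (n = 7), rested on 4 libraries above every reporter-only library, while the other 3 had 4.06 to 4.33% U. Human TUT1, a U6 snRNA uridylyltransferase, was not called, with 2.42% U ± 0.0409 (n = 3); with only libraries in the authors' table its lower U share passed (limma adjusted p = 0.0336). The single PUP-2 library had 96.4% U (95% Wilson interval 96.36 to 96.45).

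In the list of enzymes known mainly by systematic names, which also held RPN1, 11 were tested. Of these, 6, RPN1 among them, had a higher A share, and 3 a higher U share. Neither was called for NCU05588.7 or for NCU08022.7, the latter with differing construct names, and 5 had longer tails (7 when adjusted over the list alone). *C. elegans* F43E2.1 gave 89.2% U ± 4.12 (n = 3), *N. crassa* NCU04364.7 76.9% ± 10.3 (n = 4) and F31C3.2 19.5% ± 2.64 (n = 5). Single libraries of *N. crassa* NCU00538.7 and *C. albicans* C3_02760C_A had 90.8% A (95% Wilson interval 90.6 to 90.9) and 84.6% A (84.0 to 85.1).

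All groups with a higher C share were members of the CCA-adding list, named for enzymes that complete tRNA 3′ ends. Whether each member adds all of CCA was not tested. Of 4 tested, 3 passed: *S. cerevisiae* Cca1 with 76.7% ± 1.05 (n = 3; limma adjusted p = 1.67e-15), *C. elegans* HPO-31 with 64.7% ± 3.63 (n = 2; limma adjusted p = 4.19e-11) and *S. pombe* SPAC1093.04 with 58.0% ± 4.71 (n = 5; limma adjusted p = 3.12e-13). The other *S. pombe* enzyme of the list, SPCC645.10, had a lower C share, 2.15% ± 0.292, with 90.4% A ± 1.26 (n = 3). That lower C call was lost when each distinct tail was counted once, with run as a covariate, with the DADA mutants in the control, and without reporter-only replicate 2 (log2 difference −1.36, limma adjusted p = 0.0505). The single *C. albicans* CCA1 library had 54.02% C (95% Wilson interval 53.9 to 54.2).

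The longest tails among tested groups, after those of Cid1, were made by TENT4B (10.2 ± 4.70 nucleotides, n = 4), TUT7 (9.12 ± 0.986, n = 4), cutA (8.56 ± 1.38, n = 3), Cid16 (7.86 ± 1.04, n = 3) and Cca1 (7.72 ± 1.46, n = 3).

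RDE-3, a *C. elegans* nucleotidyltransferase needed for RNA silencing, was tested as isoforms a and b with mutants of each. Of 10 RDE-3 groups, 6 had a higher A share (5 when adjusted over the list alone) and 1, RDE-3a, had a higher G and U share. With RDE-3a, 32.2% ± 4.72 (SD, n = 8) of added nucleotides were G and 27.5% ± 5.04 U. The DADA mutant of RDE-3a had 90.4% A ± 1.26 (n = 4) and D189N 92.9% A ± 0.416 (n = 2), while Δ164-end had 95.5% ± 0.160 (n = 2) and Δ169-end 95.1% ± 0.0405 (n = 2). The G call of RDE-3a was lost when shares were averaged over tails (log2 difference 0.64, limma adjusted p = 0.108).

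The comparison of RDE-3a with its DADA mutant asked whether the tails depend on the residues mutated. UG or GU pairs made up 62.3% ± 9.49 of pairs with RDE-3a (n = 8, 52.6 to 76.1%) and 0.993% ± 0.220 with DADA (n = 4), a difference of 61.3 points (two-sided exact permutation p = 0.00202, the smallest the design allows). The G share differed by 27.4 points and the U share by 25.4 (exact permutation p = 0.00202 for each, the smallest the design allows), from 4.76% ± 0.834 G and 2.09% ± 0.331 U with DADA. Tails were longer by 1.21 nucleotides, at 3.60 ± 0.725 against 2.39 ± 0.0640 (exact permutation p = 0.0121). Within run 1 the UG or GU share was 54.1% against 0.893%, and within run 3 68.8% against 1.29%. Restricted to these runs and permuted within them, the difference was 57.4 points and the smallest p that could be reached was 0.05. In the authors' table the 8 RDE-3a libraries carry 5 construct names and the 4 DADA libraries 3. With libraries that share a name averaged, the smallest exact permutation p that could be reached was 0.0179.

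**Figure D2:**
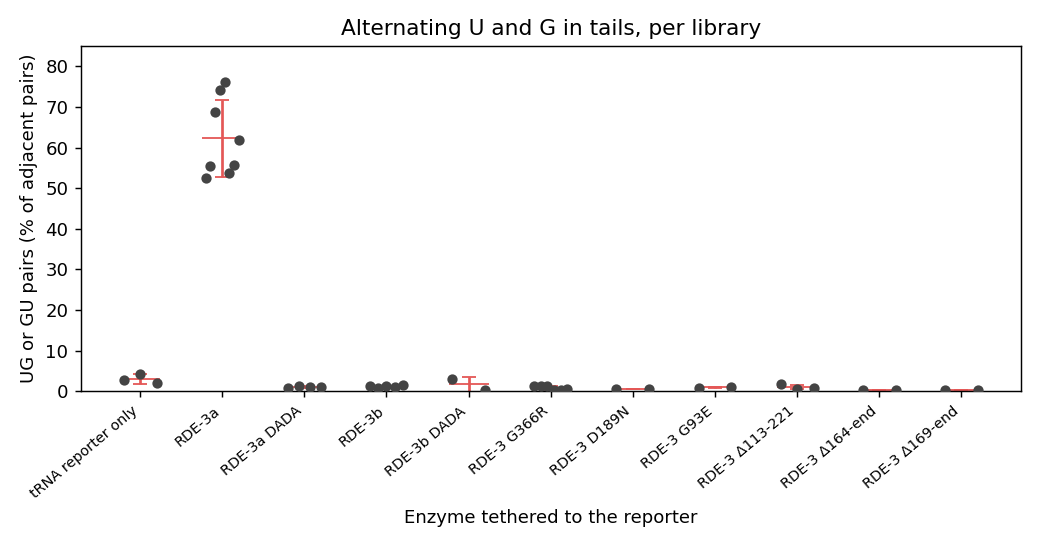
Percent of adjacent pairs that are UG or GU in each library of the RDE-3 groups and reporter only; points are libraries, horizontal lines means and vertical lines SD. The 8 RDE-3a libraries lie between 52.6 and 76.1%, above every library of the other groups.

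Of the 34 trinucleotides tested with edgeR, 11 were more frequent with RDE-3a than with DADA and 13 less frequent. UGU made up 32.9% ± 3.99 of trinucleotides with RDE-3a against 0.100% ± 0.0351 (log2 fold change 8.40) and GUG 35.6% ± 4.15 against 0.214% ± 0.153 (7.38). UGA (3.69), UUG (2.51), GUU (2.37) and GUA (2.28) were also higher, each above DADA in all 8 libraries. UUC fell by 3.08 on the log2 scale, CGG by 2.51, UUU by 2.48, GGC by 2.35, ACA by 2.22 and AAC by 2.12. Their counts, summed over all RDE-3a and over all DADA libraries, were low. These were 21 and 30 for UUC, 37 and 32 for CGG and 77 and 88 for UUU. For GGC they were 51 and 44, for ACA 57 and 39 and for AAC 66 and 45. Trinucleotide shares sum to the whole, so the rise of UGU and GUG by itself lowers the shares of the others. How much of each fall is due to this was not tested. AAA, chosen after its values were seen, fell from 91.1% ± 1.69 to 21.4% ± 7.31 (log2 fold change −2.09). The falls called but not named above were smaller: AGA (−0.77), AAG (−0.91), GUC (−1.15), CCA (−1.25), CUG (−1.36) and AGG (−1.66). Relative to AAA, these trinucleotides were not lower with RDE-3a. The UUU call rested on DADA replicate 3, without which it fell by 0.47 (edgeR adjusted p = 0.482). With DESeq2 10 were higher and 39 lower, without the filter 34 were lower, and with a replicate block on replicates 1 to 4, where 26 were tested, 6 were lower.

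The b isoform did not share these tails. UG or GU pairs were 1.19% ± 0.211 (n = 5) with RDE-3b and 1.70% ± 1.85 (n = 2) with its DADA mutant, a difference of −0.507 points (two-sided exact permutation p = 0.524). Without RDE-3b DADA replicate 1 (3.01%) the difference was 0.799. RDE-3a exceeded RDE-3b by 61.1 points (exact permutation p = 0.000777, the smallest the design allows), and by 67.6 points in run 3, 57.3 in run 6 and 52.6 in run 7. It exceeded reporter only by 59.3 points (exact permutation p = 0.00606, the smallest the design allows), and by 51.7 points in run 1 and 64.6 in run 3. In the authors' table RDE-3b and reporter only each carry 2 construct names, and RDE-3b DADA carries 1. With libraries that share a name averaged, the smallest exact permutation p for RDE-3a against RDE-3b or reporter only was 0.0476.

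Each RDE-3 mutant had few UG or GU pairs compared with RDE-3a. The share was 0.877% ± 0.512 for G366R (n = 6), 0.687% ± 0.00238 for D189N (n = 2), 0.975% ± 0.189 for G93E (n = 2), 1.08% ± 0.613 for Δ113-221 (n = 3), 0.309% ± 0.0746 for Δ164-end (n = 2) and 0.306% ± 0.0968 for Δ169-end (n = 2). Exact permutation tests, each at the smallest p its design allows, gave an adjusted p of 0.0020 for G366R, 0.0182 for Δ113-221 and 0.0222 for the rest. With libraries that share a construct name averaged, the smallest exact permutation p before adjustment was 0.00794 for G366R, 0.0179 for Δ113-221 and 0.0476 for the rest. The labels of these mutants do not give the isoform. In run 1, which held libraries of all 6 mutants, the differences from RDE-3a lay between −53.8 and −53.0 points.

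TUT4 and TUT7 are human paralogs. The U share was 31.7% ± 32.8 with TUT4 (n = 7) and 82.5% ± 2.19 with TUT7 (n = 4), a difference of −50.8 points (two-sided exact permutation p = 0.0182). TUT4 libraries spread by run, with a U share of 73.1, 73.6 and 50.1% in run 6, 12.6% in run 3 (95% Wilson interval 12.4 to 12.7) and 4.17, 4.06 and 4.33% in run 5. In the runs that hold both, the difference was −70.4 points in run 3 and −77.9 in run 5 (−75.2 over both; permuted within run, exact permutation p = 0.0333). The authors' table lacks 4 of the 7 TUT4 libraries, those of run 3 and run 5, which had the lowest U shares. The difference within runs rests on these 4 libraries. With only libraries in the authors' table, the difference was −16.96 (exact permutation p = 0.0286). With all libraries, in tails of 5 nucleotides or more, it was −45.96 (exact permutation p = 0.115).

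**Figure D3:**
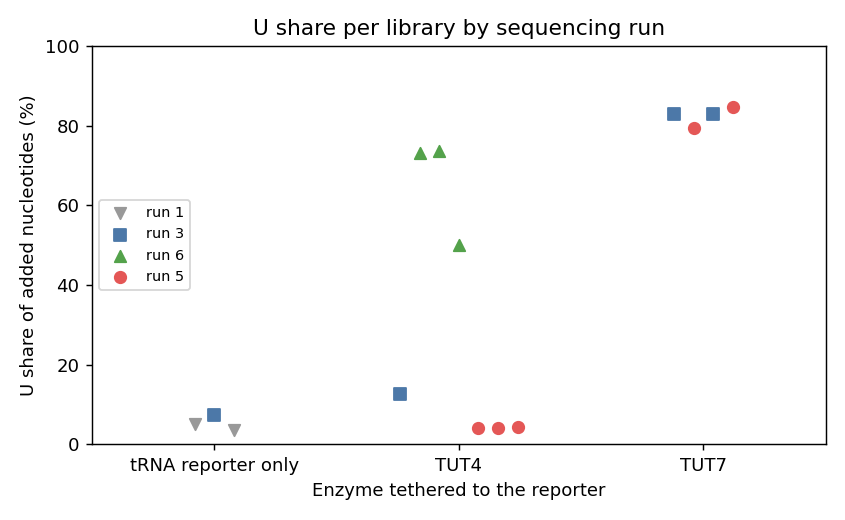
U share (percent of added nucleotides) of each reporter-only, TUT4 and TUT7 library, with the run shown by the symbol; points are libraries. TUT7 libraries lie between 79.5 and 84.7%, while TUT4 libraries of run 5 lie between 4.06 and 4.33%.

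Human TENT4A had a lower G share than its paralog TENT4B. The G share was 3.83% ± 0.472 with TENT4A (n = 3) and 7.45% ± 0.4658 with TENT4B (n = 4), a difference of −3.61 points (two-sided exact permutation p = 0.0286, the smallest the design allows). All 7 libraries were in run 5. When shares were averaged over tails the difference was −0.579 points (exact permutation p = 0.743). The 4 TENT4B libraries carry 2 construct names in the authors' table; with shared names averaged, or with any 1 library left out, the exact permutation test no longer passed, since designs of that size cannot reach 0.05.

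Each cutA library of *A. nidulans* had a higher C share than each cutB library. The C share was 5.91% ± 0.238 with cutA and 1.66% ± 0.143 with cutB (n = 3 each), a difference of 4.25 points. The exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow, and all 6 were in run 5. In the authors' table the 3 cutA libraries share 1 construct name and so do the 3 cutB libraries, so the spread is that within 1 construct each.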

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

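The tests on TUT4, on repeated heptamers in reporter-only replicate 2, and on SPCC645.10 and SPAC1093.04 were chosen after the result was seen, as were the counts over other splits and the measures of CC, CCA and U-tract ends.

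RDE-3a and RDE-3b differed in how far each stood above its DADA mutant. The excess of UG or GU pairs was 61.3 points for RDE-3a and −0.507 for RDE-3b, a difference of 61.8 points (exact permutation p = 0.000259 over 19305 permutations). Each library counted as 1 unit in these permutations, though several share a construct name. Isoform labels were exchanged within the wild types and within the mutants, so the p tests whether the isoforms can be exchanged and largely restates the 61.1 points between RDE-3a and RDE-3b; an equal excess over DADA was not tested apart from that.

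The TUT4 libraries of run 5 lacked the U tails of the other TUT4 libraries. The authors' table does not hold these run 5 libraries. A loss of U tails in the whole run is excluded, since the lowest TUT7 library of run 5 had a U share of 79.5%. Dilution by short background tails is excluded as well: in tails of 5 nucleotides or more, the highest TUT4 library of run 5 had a U share of 7.38%, against at least 85.6% in run 6. An inactive construct or another one may account for the pattern, since the highest U share of the run 5 libraries, 4.33%, lay below the highest reporter-only library, 7.42%. No biological explanation was tested.

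Reporter-only replicate 2 had a lower A share than the other reporter-only replicates, and the number of groups called for A depends on it. Repeated heptamers are excluded as the whole cause, since the gap was 12.9 points before their correction, which assumes distinct heptamers, and 12.7 after it. Greater depth may contribute: within groups with a higher A share, deeper libraries outside run 3 had a lower A share (73 libraries, r = −0.443, permutation p = 0.0113; rho = −0.370, permutation p = 0.0182; r = −0.345 without the 2 farthest libraries). Run 3 may contribute too, since its 6 libraries lay −3.85 points from the 22 other libraries of their groups (exact permutation p = 0.000109, the smallest they can give). Run 3 also holds deep libraries, so depth and run stay open, and no biological explanation was tested.

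Ends that stop before or at CCA, outside the tail measures, differed for members of the CCA-adding list. SPCC645.10 ended in untailed CCA in 78.7% ± 4.75 (n = 3) of untailed CCA and CC ends, against 53.2% ± 2.24 in reporter only, and inserts followed CC rather than CCA in 72.9% ± 3.34 (n = 5) of inserts with SPAC1093.04, against 28.1% ± 7.85. Depth and run are excluded for both: outside the CCA-adding list, libraries of the same depth and runs reached at most 62.4% and 65.8% for untailed CCA (lowest SPCC645.10 library 74.7%), and 44.3% and 22.4% for inserts after CC (lowest SPAC1093.04 library 68.2%). Repeated heptamers are excluded as the whole cause for SPCC645.10: after their correction, which assumes distinct heptamers, its lowest library was at 82.0%, against at most 60.0% in the 7 reporter-only and DADA libraries whose counts lay below the number of heptamers. SPAC1093.04 may add C to ends that stop at CC, since at least 83.5% of its nucleotides after CC were C against at most 36.4% in reporter only. This C share is not particular to it: it was 79.9% ± 7.33 with Cca1 and 61.3% ± 0.720 with HPO-31. With those enzymes fewer inserts followed CC, 4.99% ± 1.83 and 8.63% ± 3.28. An A added to a CC end would read as CCA, however, so the definition of the ends favours other nucleotides after CC in every group. SPCC645.10 might add A to CC ends, but its 26.4 points above the reporter-only and DADA libraries (exact permutation p = 0.00455) only restate why it was singled out. That stays untested.

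Among other enzymes, the untailed CCA share was 73.0% ± 2.19 with Cca1 and 68.0% ± 5.19 with HPO-31, with every library above the highest reporter-only library at 55.5%, whereas with SPAC1093.04 it was 48.8% ± 1.96 (n = 5), with every library below the lowest reporter-only library at 51.0%. Counts of these abundant ends may be compressed, which would draw the shares toward each other. After the correction for repeated heptamers, which assumes distinct heptamers, reporter only was at 62.6% ± 8.05 (56.1 to 71.6%). Cca1 was then at 84.6% ± 2.49, HPO-31 at 75.7% ± 1.17 and SPAC1093.04 at 48.3% ± 3.02. Inserts followed CC in 45.0% ± 3.35 of inserts after CC or CCA with TUT7 and in 41.8% ± 3.56 with PUP-1, with every library above the highest reporter-only library at 36.3%.

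Among inserts found where none of CCA, CC or C ended the reporter and that opened with 4 or more U, the share that went on with 3 or more A was 4.75% ± 1.42 in reporter only, 6.23% at most. It was 70.7% ± 0.193 (n = 2) with TENT2, 30.8% ± 1.81 (n = 3) with cutB, 25.3% ± 7.33 (n = 4) with C53A5.16 and 20.2% ± 4.13 (n = 6) with Cid12. The mean was 18.2% ± 0.152 (n = 2) with RDE-3 Δ164-end, 18.2% ± 7.70 (n = 3) with Cid14, 16.8% ± 7.05 (n = 5) with SPAC1093.04 and 16.8% ± 5.14 (n = 4) with TENT4B. It was 16.4% ± 2.66 (n = 3) with Cid11, 16.3% ± 8.19 (n = 4) with ZK863.4 and 14.1% ± 1.27 (n = 2) with RDE-3 Δ169-end. The means of TRF4 (24.4% ± 24.2, libraries at 7.26 and 41.5%) and CR_03940W_A (17.1% ± 10.1, libraries at 9.90 and 24.2%) each rest on 1 of their 2 libraries. These groups were listed because every library lay above the highest reporter-only library and the mean was at least 2 times that value.

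The A share of TENT4B replicate 2 was 87.1%, apart from the other TENT4B libraries at 89.1 to 89.3%. It was the only one to stand apart in 21 sets of a group and a measure, and chance gives about 1 in 20.

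Other splits of the libraries into groups of the same sizes were drawn 100 times, the real one included. For A, 2 of them gave as many calls as the real 25, and the highest other gave 26, more than the real split. The share of splits is under 0.05, but the size of the count does not stand above that of the other splits. Chance is therefore not excluded for this count. Only the real split gave as many for C (1 of 100, real 3, highest other 1), U (real 10, highest other 3) and longer tails (real 20, highest other 0). The same held for trinucleotides higher (real 11, highest other 0) and lower with RDE-3a (real 13, highest other 2). Other splits mix unlike libraries within a group, which widens the spread and tends to lower the number of calls. These counts therefore speak only against no difference between groups, and not for any single call. For G, 3 of them gave as many as the real 1, and the highest other gave 19, several times the real count. The share is again under 0.05 and the size again does not stand above the other splits, so chance is not excluded for this count either. Within each split of the screen, the real one included, all groups were compared with 1 shared control group. The calls of a split are therefore not independent, and many can arise together. What gave the high counts of other splits, for A as for G, was not examined.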

How the results depend on the processing

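The correction for repeated heptamers, the use of libraries in the authors' table and the averaging of libraries that share a name were chosen after the result was seen. Of 453 values of the 24 comparison results under alternatives, 407 kept their direction and side of the threshold or, for counts, lay within 1.5 times the reported count, 35 became weaker, 9 counts moved and 2 reversed. Of 738 values for 48 single enzymes and trinucleotides, 704 kept both, 28 became weaker, 2 stronger and 4 reversed. The share of variance explained by enzyme stayed between 93.4 and 98.0% in every alternative run. Groups with longer tails numbered 14 to 26 (reported 20), those with a higher U share 9 to 10 and a higher C share 3 to 4, and trinucleotides higher with RDE-3a 10 to 13. The cause was not tested unless stated.

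The number of groups with a higher A share was 12 in tails of 3 nucleotides or more and 11 with the DADA mutants in the control; leaving out each reporter-only replicate gave 14 (without replicate 2) to 27. For G it was 2 in tails of 3 nucleotides or more, 0 when shares were averaged over tails and 2 with the DADA mutants in the control. Trinucleotides lower with RDE-3a numbered 34 without the filter and 39 with DESeq2, which tested more trinucleotides, and 6 with a replicate block on replicates 1 to 4, which also left out 4 RDE-3a libraries and tested 26.

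With replicate number as a block and an exact sign-flip test, too few pairs limited p (for G366R, only after adjustment over the 6 mutants). RDE-3a exceeded DADA by 61.8 points in UG or GU pairs, 27.6 in G, 26.0 in U and 1.41 nucleotides in length, and in UG or GU pairs RDE-3b by 64.3 and reporter only by 56.0. The block differences from RDE-3a were −62.6 for G366R, −53.4 for D189N, −53.1 for G93E, −57.9 for Δ113-221, −53.8 for Δ164-end and −53.8 for Δ169-end. For TUT4 minus TUT7 the block gave −30.2 and for TENT4A minus TENT4B −3.82. The TUT4 block held only the 4 replicate numbers shared with TUT7. It left out the TUT4 libraries with the lowest U shares, which by itself makes that difference smaller. Between RDE-3a and DADA, deviations of libraries with the same replicate number correlated weakly, from −0.212 to 0.261, so no pairing was seen there.

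Within the runs that hold both groups, fewer libraries limited p (for G366R, only after adjustment over the 6 mutants; its unadjusted exact permutation p was 0.0238). RDE-3a then exceeded DADA by 57.4 points, 25.9 in G, 23.7 in U and 1.13 nucleotides, and reporter only by 56.0. The differences from RDE-3a were −57.0 for G366R, −53.4 for D189N, −53.1 for G93E, −53.0 for Δ113-221, −53.8 for Δ164-end and −53.8 for Δ169-end.

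TUT4 minus TUT7 was −45.96 in tails of 5 nucleotides or more. TENT4A minus TENT4B was −0.579 when shares were averaged over tails, −3.61 with shared names averaged, and −3.82 to −3.35 with each replicate left out, where fewer libraries limited p. RDE-3b minus DADA reversed to 0.815 with each distinct tail counted once, and leaving out each replicate gave −1.81 to 0.799, where a lone DADA library was assumed to vary like the other groups. Single enzymes that reversed in A share were TENT4B (−0.064 in tails of 3 nucleotides or more) and Cid14 (−0.97 in tails of 3 or more, −0.11 in tails of 5 or more, −0.46 with the DADA mutants in the control); with each distinct tail counted once, Cid14 was instead called higher (1.96, limma adjusted p = 0.000884).

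Depth limits the rare pairs: the smallest library used had 244 tails.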

Other observations

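The measures of tail order, tail starts and inserts after CC were chosen after the result was seen, and none was tested.

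RDE-3a tails of 5 nucleotides or more were built mainly of alternating U and G. UG or GU made up 81.7% ± 5.36 (SD, n = 8) of their pairs, against 2.07% ± 0.340 with DADA and 4.66% ± 1.08 in reporter only. Strict alternation of U and G held for 61.0% ± 6.09 of these tails (50.7 to 67.8%) and for 0 of 1686 with DADA, which allows a share of up to 0.178% (3 counts over the group, counting error only). Of the RDE-3a tails of this length, 46.2% ± 6.18 started with G, 38.1% ± 5.23 with U and 15.3% ± 5.60 with A, whereas 96.6% ± 0.397 (n = 4) of DADA tails of this length started with A.

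Of 4 tested members of the CCA-adding list, 3 often had tails that began with a further CCA. This held for 74.6% ± 4.24 of Cca1 tails, 39.5% ± 2.72 of HPO-31 tails and 10.6% ± 1.84 of SPAC1093.04 tails, against 0.441% ± 0.201 with SPCC645.10 and 0.634% ± 0.353 in reporter only. It also held for 38.8% of tails of *N. crassa* NCU08022.7 replicate 1, whose construct name in the authors' table differs from that of the other replicates, against 0.410% and 0.549% in the other replicates. That replicate had 47.1% C (95% Wilson interval 46.8 to 47.4).

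Inserts after CC were also rich in U with TUT7 and PUP-1. Of nucleotides added after CC, 91.2% ± 1.15 were U with TUT7 and 92.4% ± 1.35 with PUP-1, against 21.9% ± 1.34 in reporter only. An A added to a CC end would read as CCA, which favours other nucleotides after CC in every group. Of inserts of 5 nucleotides or more, 56.9% ± 1.03 followed CC with TUT7, 49.8% ± 4.65 with PUP-1 and 72.7% ± 4.24 with SPAC1093.04. In reporter only it was 7.98% ± 6.90, with libraries from 2.80 to 15.8%.

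In tails of 5 nucleotides or more, Cid14 had 19.7% G ± 0.758, and F31C3.2 had 61.1% A ± 0.423 and 26.4% U ± 0.626.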
